A study of Homo sapiens with 20 samples.

How the data were processed

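Primary human monocytes, isolated from bone marrow by density gradient and negative selection, were cultured overnight with GM-CSF, IL-4 and PGE2 and then encapsulated for 3 days in hydrogels. The gels were soft or stiff (elastic moduli of about 0.75 and 7.5 kPa per the labels) and viscous or elastic, which made 4 groups. RNA was measured with a custom nanoString panel of myeloid markers, an assay that counts colour-coded probes without amplification. There were 20 samples from 2 experiments, and each experiment held all 4 groups. Elastic soft gels had 6 samples, elastic stiff gels 4, viscous soft gels 5 and viscous stiff gels 5. The labels do not state which donor or culture each sample came from, so the samples were treated as replicates of their group.

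The authors deposited 1 table of 273 rows by 20 samples with values in log2. The labels do not state how the values were normalised. The deposited values were checked for their unit: 2 to the power of each value fell on whole multiples of a step that differed between samples, within 0.02 of a whole number. One step served 177 rows (the first probe set), another step served 91 rows (the second probe set), and 5 rows matched the plain mean of a multiple of each within 0.0002. All 100 values of those 5 rows matched, where about 20.5 would match by chance. They carry the labels ALAS1, ELANE, ICOS, SCIN and TAZ. In the 12 samples where all 5 could be split into both sets, their geometric mean was 8.01 in log2 in each set, which gives the scaling that was inferred from the values. The 7 empty cells, in 5 rows, were left empty in the fits; the labels do not state why they are empty, and the recovered counts took them as 0.

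Counts recovered by dividing by the step summed to between 110406 and 739485 per sample in the first probe set and between 55527 and 299648 in the second. These recovered counts were used for depth, for thinning and for 1 alternative only. Replicates of the same group and experiment differed by more than counting error, with a chi-squared per degree of freedom from 2.38 to 117.5, so the spread between replicates and not the counting set the precision.

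A row was tested when its linear value was at least 20 in at least 4 samples. That left 258 rows, with 11 below the filter and 4 control rows (labelled purespike1.1, purespike2.1, purespike3.1 and Reserved) left out. The log2 values were used as deposited, without a further log or pseudocount. A linear model with a mean for each of the 4 groups and an experiment term was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend=TRUE) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg over the 258 rows, with a threshold of 0.05. The comparisons were viscous minus elastic and stiff minus soft, each averaged over the other factor with equal weight, their interaction, and the 4 simple effects. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.

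Of 24 gene lists fixed before the data were examined, 14 had at least 3 tested rows and were tested with limma's camera (preset correlation of 0.01 and estimated correlation) and fry, adjusted over the lists within a comparison. Lists were matched to row labels by name.

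The fit was tested on simulated data with 258 rows, the same groups and 30 changed rows per fold size, over 20 runs. It found 97.5% of 2-fold changes for both main effects, 76.7% for the interaction and, for the simple effects, 89.2% for viscoelasticity in soft gels, 88.3% in stiff gels, 89% for stiffness in viscous gels and 86.2% in elastic gels. False calls made up 2.58% of calls for the interaction, the lowest share, and 3.85% for stiffness in viscous gels, the highest. The simulated noise was normal and independent between samples and between rows, and each planted change was the same in both experiments. These shares hold under those conditions, which the real samples need not meet.

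Named rows followed a rule fixed before the data were examined: for each main and simple effect, up to 10 rows with the largest rise and 10 with the largest fall among those past the threshold with the same sign in both experiments; up to 4 members per list with the smallest p in the main effects; a fixed list of markers; and, for the interaction, the 10 rows with the smallest adjusted p. From the rows this rule gave, the ones printed were picked after their values were seen. For the interaction, the rows labelled CD14 and FOS were outside its 10 and were chosen after their values were seen.

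Alternatives covered the filter, a pseudocount, 4 scalings, the experiment term, each experiment alone, a replicate block, the variance model, a fold threshold and leaving out each sample. Added after seeing the data were voom on the recovered counts, each probe set alone, leaving out 2 samples with low totals and 2 readings of the row labels. No row was renamed: every row is called by the label the table gives it.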

Results

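The table held log2 nanoString values for 273 rows in 20 samples of monocytes kept for 3 days in 4 kinds of hydrogel: elastic soft (n = 6), elastic stiff (n = 4), viscous soft (n = 5) and viscous stiff (n = 5). Recovered totals per sample in experiment 1 ran from 110406 to 329683 counts in the first probe set and from 91087 to 272779 in the second. In experiment 2 they ran from 154798 to 739485 and from 55527 to 299648. The series design text states the question as the effect of mechanical cues on monocyte transcription. The SEs and p-values below treat each sample as independent. If samples of an experiment shared a donor or culture, these values would overstate the certainty. The labels give neither, so only the 2 experiments are known to be separate repeats.

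A limit on the row labels applies to every row named here. Among the 106 rows with labels from H to P, rows named for widely abundant transcripts lay above rows named for restricted ones in 0.498 of pairs, where 0.5 is no order. Outside those labels the share was 0.85. Reading the values of the H to P rows 2 rows further down raised their share to 0.946. Counts of changed rows use the labels only to leave out the 4 control rows. Names rest on the labels, so each is given as the row labelled so, and those with labels from H to P are marked as such.

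**Figure D1:**
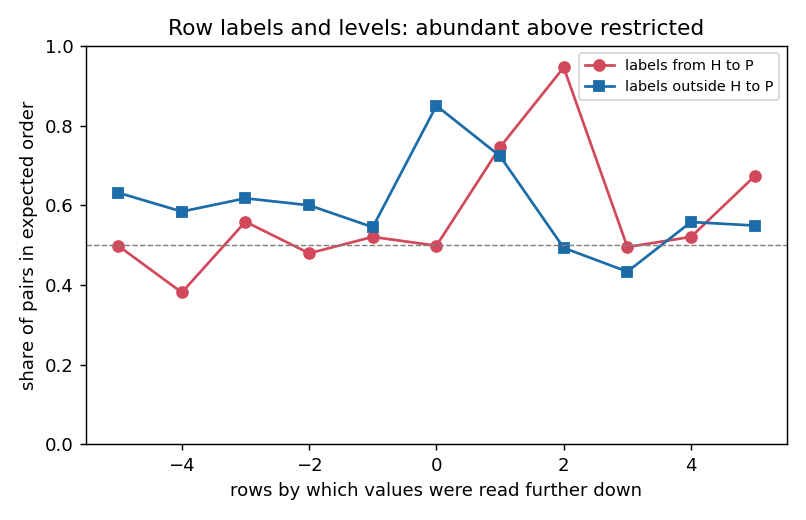
Share of pairs in which a row named for an abundant transcript had a higher median log2 value than a row named for a restricted one (vertical axis), against the number of rows by which values were read further down (horizontal axis). Labels from H to P peak at 0.946 for a displacement of 2 and the other labels at 0.85 for a displacement of 0.

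After each row was centred by experiment, the first principal component held 60.7% of the variance. All 4 elastic stiff samples had scores from 12.5 to 14.7 on it, and the other 16 samples lay at or below 0.102. Before centring, the experiment accounted for 96.8% of the variance of the first component, and 158 of 258 rows differed between the experiments.

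**Figure D2:**
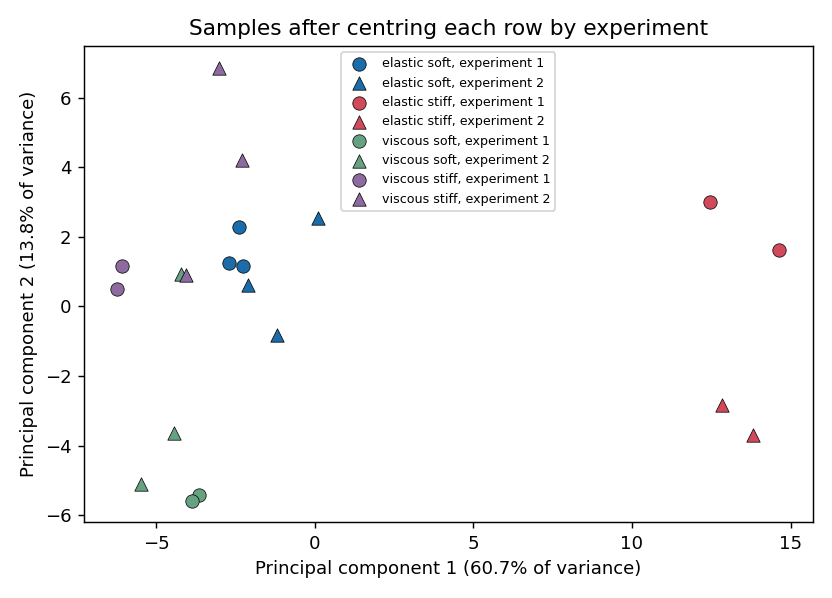
Scores of the 20 samples on the first 2 principal components (no unit) of the log2 values after centring each row by experiment; colours are groups, circles are experiment 1 and triangles experiment 2. The 4 elastic stiff samples lie at 12.5 or more on the first component and the other samples at or below 0.102.

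Viscous gels were compared with elastic gels, averaged over stiffness, to ask which rows change with viscoelasticity. Of 258 rows, 125 changed, 37 higher and 88 lower in viscous gels, and 27 changed over 2-fold. In experiment 1 alone 154 rows changed and in experiment 2 alone 104, and the fold changes of the experiments correlated across rows (r = 0.799; rows are not independent replicates). The split between higher and lower rested on the scaling: 29.6% of changed rows were higher as deposited, 55.7% after centring on the sample median, 46.6% after quantile normalization, 43% with TMM factors and 16.3% with housekeeping scaling, which rests on 1 row. The row labelled CD1A, named for a lipid-presenting molecule of dendritic cells, fell by 1.48 on the log2 scale (SE 0.0888, adjusted p = 3.25e-11). The row labelled CSF3R, named for the G-CSF receptor, rose by 1.44 (SE 0.106, adjusted p = 2.65e-10). Among the other rows that fell were those labelled CD1B, CCR7 and TXN, with log2 changes of -1.47, -1.22 and -1.27, and CD86 with -0.60. The row labelled BEX1 rose by 1.94. Within labels from H to P, the rows labelled MPO and MRC1 fell by 2.79 and 2.07, and the row labelled IL10 rose by 1.35. All these changes are averages over soft and stiff gels and need not hold in both. The size of the change differed between experiments for the rows labelled BEX1 and MRC1 (adjusted p = 0.013 and 0.022, limma).

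Stiff gels were compared with soft gels, averaged over viscoelasticity. Here 99 rows changed, 71 higher and 28 lower in stiff gels, and 17 changed over 2-fold. Experiment 1 alone gave 122 rows and experiment 2 alone 84 (r = 0.735 across rows). The share of changed rows that were higher was 71.7% as deposited, 45% after median centring, 52.9% after quantile normalization, 58.3% with TMM factors and 87.5% with housekeeping scaling. The row labelled CCR7, named for a chemokine receptor of mature dendritic cells, rose by 1.37 (SE 0.118, adjusted p = 1.12e-08). The row labelled A2M rose by 1.06. The row labelled FCGR1A, named for a high-affinity Fc receptor, was 2.15-fold lower (SE 0.197 in log2, adjusted p = 0.000103), and fell by 0.28 in experiment 1 and by 1.79 in experiment 2 on the log2 scale. The row labelled CSF3R fell by 0.80. Each of these changes is an average over elastic and viscous gels and need not hold in both. The rows labelled FCGR1A and CSF3R were not among the 6 rows that fell with stiffness in viscous gels.

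The interaction asked whether the effect of one factor depended on the other. It was past the threshold in 113 rows, 64 positive and 49 negative, in 128 in experiment 1 alone and in 102 in experiment 2 alone (r = 0.769 across rows). The share of positive interactions was 56.6% as deposited, 73.2% after median centring, 66.3% with housekeeping scaling, 52.6% after quantile normalization and 47.2% with TMM factors. In 93 rows the elastic stiff group differed from each of the other 3 groups in the same direction, higher in 60 and lower in 33. The row labelled CCR7 averaged 10.08 ± 0.52 (log2, SD, n = 4) in elastic stiff gels, 7.58 ± 0.39 (n = 6) in elastic soft gels, 7.56 ± 0.53 (n = 5) in viscous soft gels and 7.80 ± 0.60 (n = 5) in viscous stiff gels. Its interaction was -2.26 (SE 0.235, adjusted p = 1.64e-07). The row labelled VCAN, named for the proteoglycan versican, averaged 5.76 ± 0.29 (SD, n = 4) in elastic stiff gels, against 7.90 ± 0.35 (n = 6), 7.42 ± 0.77 (n = 5) and 8.38 ± 0.27 (n = 5) in elastic soft, viscous soft and viscous stiff gels. Its interaction was an 8.55-fold ratio (SE 0.306 in log2, adjusted p = 7.61e-08). The elastic stiff values of this row lay little above the tenth percentile of second-set values (5.12 in experiment 1 and 5.05 in experiment 2). The sizes of its changes against elastic stiff gels, here and below, are therefore uncertain. The rows labelled FOS and CD14 had interactions of 2.13 and 1.38. Within labels from H to P, the rows labelled MPO, MRC1, IER3 and LIF had interactions of -6.65, -5.68, -2.87 and -2.28. The size of the interaction differed between experiments for those labelled MPO and MRC1 (adjusted p = 0.0206 and 0.00681, limma).

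**Figure D3:**
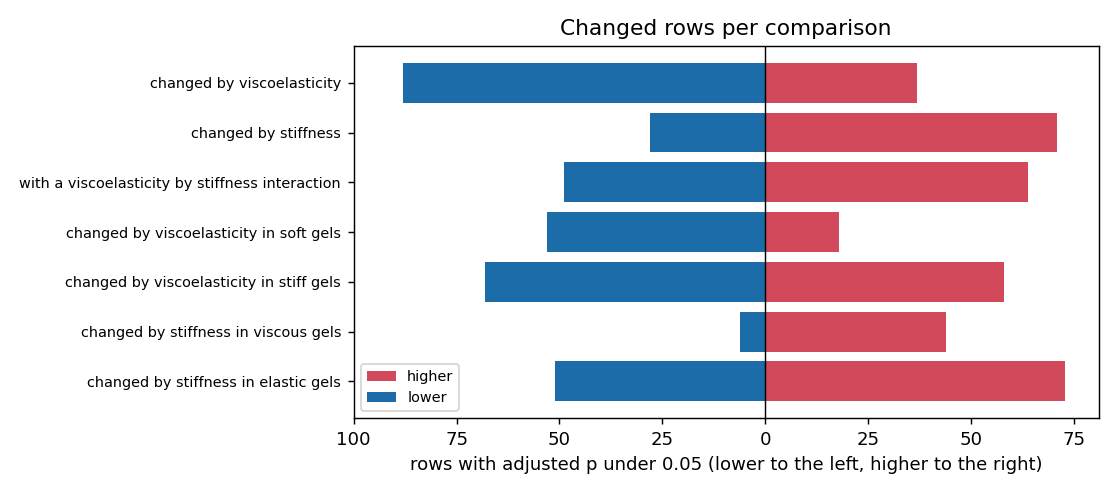
Number of rows with an adjusted p under 0.05 (horizontal axis) in each comparison, higher to the right and lower to the left. Viscoelasticity in stiff gels has the most rows, 126, and stiffness in viscous gels the fewest, 50.

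Viscoelasticity in soft gels changed 71 rows, 18 higher and 53 lower in viscous soft gels, and 7 of them over 2-fold. The share that was higher was 25.4% as deposited and between 6.62% and 43.5% under the other scalings, which moved the count from 71 to as many as 136. Fold changes correlated weakly between experiments (r = 0.396 across rows). The row labelled CST7, named for cystatin F, rose by 1.12 (SE 0.156, adjusted p = 4.12e-05), and all 5 viscous soft samples were above the elastic soft mean of their experiment. The rows labelled CTSS, FOS, CD163 and CD1B fell by 0.90, 0.93, 0.84 and 0.78, each in 5 of 5 viscous soft samples. For those labelled CTSS and FOS the size of the fall differed between experiments (adjusted p = 0.0392 each, limma).

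Viscoelasticity in stiff gels changed 126 rows, 58 higher and 68 lower in viscous stiff gels, and 65 of them over 2-fold (r = 0.849 between experiments, across rows; the effect differed between experiments in 59 rows). After median centring 67.5% of 163 changed rows were higher, against 46% as deposited. The rows labelled VCAN, FCGR1A and CSF3R were higher by 2.57, 2.39 and 2.29. The row labelled ARG1 was also higher, but its elastic stiff values, 4.90 and 4.27 in experiment 1 and 2.79 and 2.69 in experiment 2, lay near the tenth percentile of first-set values (4.78 and 2.71), so no size is given for its change. The rows labelled TXN, CCR7, CD1A, CD1B and CD80 had log2 changes of -2.54, -2.35, -2.20, -2.16 and -1.75, and the row labelled CD274 was 2.84-fold lower. Each of these rows, ARG1 included, moved in that direction in 5 of 5 viscous stiff samples against the elastic stiff mean of the same experiment. For those labelled FCGR1A, CD1A, CD1B, CD80 and CD274 the size of the change differed between experiments (adjusted p from 0.00954 to 0.0470, limma). Of the 71 rows changed in soft gels, 44 also changed in stiff gels, 35 of them in the same direction, where independence would give 18.

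Stiffness in viscous gels changed 50 rows, 44 higher and 6 lower in viscous stiff gels, and 5 of them over 2-fold. This comparison was the least stable. Experiment 1 alone gave 79 rows and experiment 2 alone 7, r between experiments was 0.31 across rows, and the count was 23 without viscous soft experiment 1 replicate 1 and 86 without viscous soft experiment 2 replicate 2. As deposited 88% of changed rows were higher, and between 51.4% (of 35 rows, quantile normalization) and 97.7% (of 130 rows, housekeeping scaling) under the other scalings. The row labelled VCAN rose by 0.95 (SE 0.214, adjusted p = 0.00615), by 1.60 in experiment 1 and 0.52 in experiment 2. The rows labelled CD14, CTSS and CXCL3 rose by 0.63, 0.68 and 0.76 and the row labelled CST7 fell by 0.71, each in 5 of 5 viscous stiff samples. The size of the rise of the row labelled CXCL3 differed between experiments (adjusted p = 0.0301, limma).

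Stiffness in elastic gels changed 124 rows, 73 higher and 51 lower in elastic stiff gels, and 54 of them over 2-fold (r = 0.846 between experiments, across rows; the effect differed between experiments in 60 rows). After median centring 32.5% of 154 changed rows were higher, against 58.9% as deposited. The rows labelled CCR7, TXN, A2M, CD1B, CD1A, CD80, CD274 and CD86 rose by 2.50, 2.25, 1.74, 1.66, 1.60, 1.45, 1.36 and 0.53. The rows labelled FCGR1A, VCAN, CSF3R, FOS, CCR2 and CD14 fell by 2.56, 2.14, 1.64, 1.40, 1.30 and 0.75. Each moved in that direction in 4 of 4 elastic stiff samples. For the rows labelled FCGR1A, CD1A, CD80, CCR2 and CD14 the size of the change differed between experiments (adjusted p from 0.000251 to 0.0247, limma). The row labelled ALDH1A2 also rose, to a mean of 7.52, but its means of 5.31, 4.65 and 4.85 in elastic soft, viscous soft and viscous stiff gels lay near the tenth percentile of second-set values (5.12 in experiment 1 and 5.05 in experiment 2), so no size is given for its changes. The rise of the row labelled CD86 was no longer past the threshold after median centring (log2 change 0.23). Of the 50 rows changed in viscous gels, 29 also changed in elastic gels, 10 in the same direction, where independence would give 13.6, and 19 in the opposite one.

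**Figure D4:**
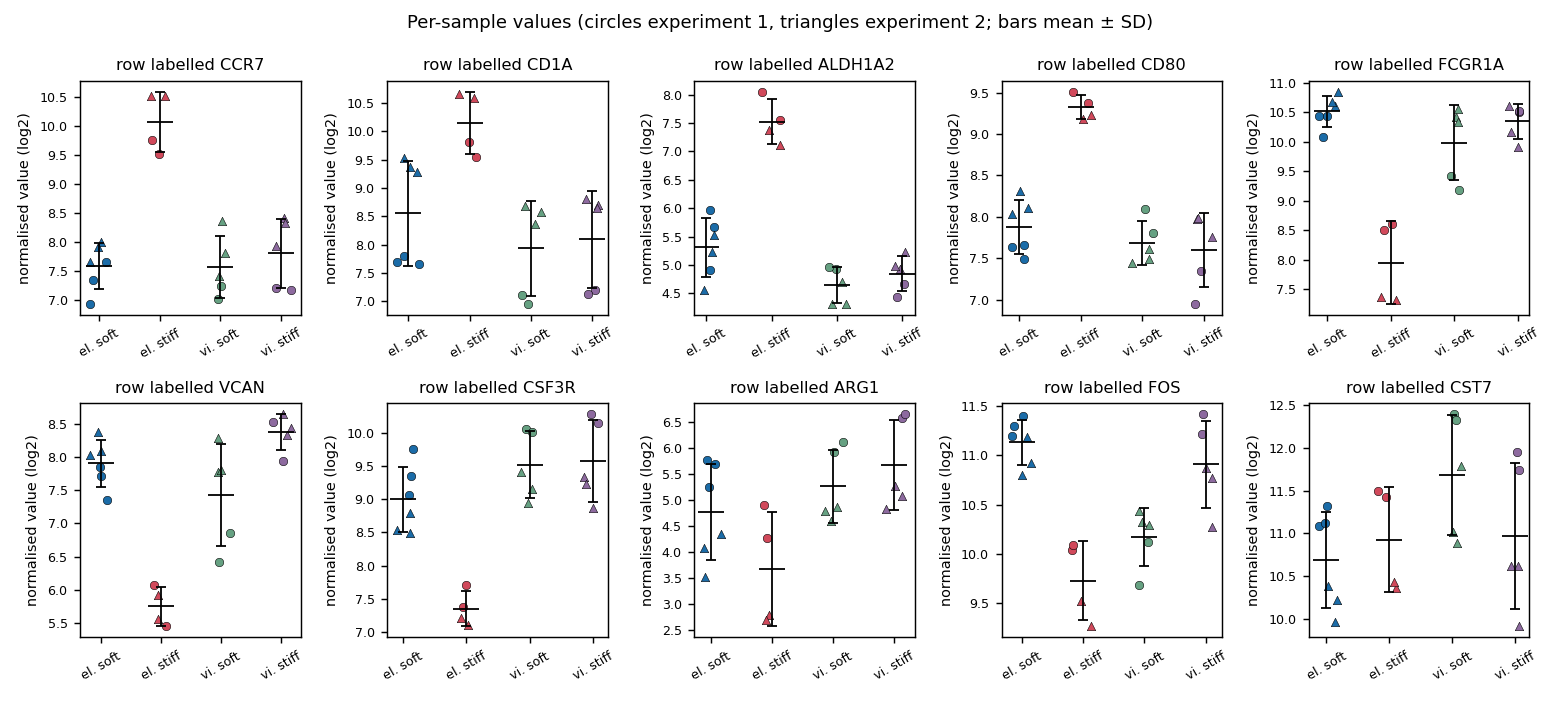
Log2 values per sample (vertical axis) in the 4 groups (horizontal axis) for 10 rows with labels outside H to P; bars are the mean and SD, circles experiment 1 and triangles experiment 2. In the row labelled CCR7 the elastic stiff mean is 10.08 and the other group means lie between 7.56 and 7.80.

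Of the 14 lists tested in 7 comparisons, camera with the preset correlation gave 4 results past the threshold. The classical monocyte list stood out upward in the interaction (mean of 9 rows 1.33, adjusted p = 0.0331) and in viscous against elastic stiff gels (1.08, adjusted p = 0.0413). The dendritic cell identity list (mean of 12 rows -0.45, adjusted p = 0.046) and the MHC class II list (mean of 10 rows -0.55, adjusted p = 0.00751) stood out downward in viscous against elastic soft gels. All members of the MHC class II list but the row labelled CTSS have labels from H to P, so that result rests on those labels. With the labels from H to P read 2 rows down it was also past the threshold with the preset correlation (mean -0.57) and not with an estimated one. Since these labels stand next to each other, most rows read so are members as labelled too. That reading therefore could not test whether the result depends on the labels. With an estimated correlation none of the 4 was past the threshold, with adjusted p-values of 0.873, 0.641, 0.419 and 0.419. Over all rows tested, 6, 6, 7 and 7 members of these lists were past the threshold in those comparisons (1 of the second 6 was lower), and 7, 6, 10 and 9 adjusted over the list alone. By fry, which asks whether a list's rows move one way and does not compare them with other rows, 8, 9 and 8 lists were past the threshold for viscoelasticity, stiffness and the interaction, and 6, 7, 9 and 10 for viscoelasticity in soft and stiff gels and stiffness in viscous and elastic gels. The median and the mean of a list differed in sign in 11 of the 98 list results, such as the macrophage list for the interaction (median 0.19, mean -1.52); none of the 4 camera results was among them. Some rows labelled for granulocytes moved with the classical monocyte list and 1 moved against it. Those labelled CTSG, CEACAM8 and CXCR2 were lower in elastic stiff gels than in each other group, by at least 17.5-fold, 1.79-fold and 1.69-fold, the last 2 being members of the granulocyte and progenitor list. The row labelled MPO, also a member and within labels from H to P, was at least 23.7-fold higher there. As labelled, that list was not past the threshold in viscous against elastic stiff gels (mean -0.25, camera adjusted p = 0.71, fry adjusted p = 0.285). Its 5 members labelled outside H to P had a mean of 0.93 there (fry adjusted p = 0.0028, camera adjusted p = 0.261). Of these, 3 were past the threshold, all higher. The member labelled ELANE is also 1 of the 5 rows whose geometric mean the inferred scaling holds fixed, so its change is tied to theirs. These list results use the labels as given.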

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

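The tests in this part on a single scaling factor, on the value of 1 count and on other splits of the samples were chosen after the results were seen; the thinning test was written before its result.

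The effect of viscoelasticity differed between soft and stiff gels in 113 rows by the interaction term, with the elastic stiff samples apart from the other groups. Deeper counting did not account for it: with every sample thinned to the smallest totals, 97 rows had an interaction, against 111 of the same 253 rows unthinned. A single scaling factor per sample moves all rows one way, but 20 rows were over 2-fold lower in elastic stiff than in elastic soft gels and 34 were over 2-fold higher. What stays open is the gel itself, which the design names and which was not tested apart from other differences between gels, such as recovery or survival of cells. A mixture of cell types stays open too: in viscous against elastic stiff gels the granulocyte and progenitor list had a mean of -0.25 and the T and NK list 0.26, with camera adjusted p-values of 0.71 each. The granulocyte mean depends on the labels: its 5 rows labelled outside H to P had a mean of 0.93 (fry adjusted p = 0.0028, camera adjusted p = 0.261), and the displaced labels gave 1.39 (fry adjusted p = 5.67e-06, camera adjusted p = 0.0627). With so few rows and the labels in doubt these values neither show nor exclude one.

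Whether other splits of the samples within experiments give as many rows was tested by refitting them. Each real count was the only one of its splits that large (1 split in each of the 7 comparisons). Of 100 splits each, the real counts and the highest of the others were 125 and 85 for viscoelasticity, 99 and 1 for stiffness, 113 and 24 for the interaction, 71 and 63 for viscoelasticity in soft gels and 124 and 64 for stiffness in elastic gels. Of 60 splits each, they were 126 and 112 for viscoelasticity in stiff gels and 50 and 49 for stiffness in viscous gels. In each comparison under 0.05 of the splits reached the real count, by the narrowest gap for stiffness in viscous gels. The splits treat single samples as independent. Samples that share a donor or culture would not be, and the labels give neither, so these splits cannot exclude chance in that case. For the interaction all 4 groups were shuffled, so that test asks about any group difference and not about an interaction.

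The experiments differed in their effects, by a test of the difference itself, in 26 rows for viscoelasticity, 36 for stiffness and 48 for the interaction. Among the simple effects they differed in 24 and 59 rows for viscoelasticity in soft and stiff gels and in 18 and 60 for stiffness in viscous and elastic gels. The 2 experiments may differ in donor, gel batch or run, none of which the labels give. Levels near background differed too, and whether those rows are the ones whose effects differed was not tested: the 18 dimmest rows of the first probe set had geometric mean values of 20.6 in experiment 1 and 4.30 in experiment 2. The value of 1 count alone did not account for this, since their mean recovered counts also differed, by a ratio of 2.39. No biological explanation was tested.

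One total lay far from the others of its group: the first probe set total of viscous stiff experiment 2 replicate 3 was 590227, and the nearest was 219146. This was 1 of 184 groups tested, where chance gives about 1 in 20. The group pooled both experiments, which differed in depth. In experiment 2 the other groups had first-set totals from 464312 to 739485, so 590227 was not unusual there. Replicates 1 and 2 of viscous stiff experiment 2, at 219146 and 154798, lay below that range.

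The 4 control rows, left out of the tests, held signal above zero: log2 values of 10.22 for the row labelled purespike1.1, 8.54 for purespike2.1, 6.62 for purespike3.1 and 7.22 for Reserved. The row labelled Reserved was higher by 0.67 in elastic stiff than in elastic soft gels (adjusted p = 0.00208, limma), and all 3 spike rows were lower there, with log2 changes of -0.53 for purespike1.1 (adjusted p = 0.00781), -0.40 for purespike2.1 (adjusted p = 0.021) and -0.37 for purespike3.1 (adjusted p = 0.0951). The spike labels begin with P and stand in the part of the table where the labels are in doubt, so which probes these rows hold is uncertain. No explanation was tested.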

How the results depend on the processing

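Voom, each probe set alone, leaving out the samples with the smallest second-set totals (55527 and 65677) and the label readings were chosen after seeing the data. Named rows were mostly called ones picked with values known, so their stability is partly by construction: of 103, 0 reversed. In 4048 of their alternative values the call stayed and in 123 it was lost. For TMM and housekeeping scaling, and wherever no reason is given, the cause was not tested.

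The counts for viscoelasticity, stiffness, the interaction, viscoelasticity in stiff gels and stiffness in elastic gels stayed within 1.5 times under each setting except the fold threshold and a probe set alone. Requiring a change over 2-fold left 27, 17, 63, 7, 65, 5 and 54 rows in the order of the report (viscoelasticity, stiffness, interaction, viscoelasticity in soft and stiff gels, stiffness in viscous and elastic gels). With fewer rows tested, the first probe set alone (166 rows) gave 79 for viscoelasticity, 60 for stiffness, 44 and 77 for viscoelasticity in soft and stiff gels and 76 for stiffness in elastic gels; the second alone (87 rows) gave 45, 43, 36, 29, 46, 15 and 44.

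Viscoelasticity in soft gels gave 136 rows with housekeeping scaling, which rests on 1 row, 33 without the experiment term and 109 with sample weights. Stiffness in viscous gels gave 130 with housekeeping scaling, 32 with TMM, 14 without the experiment term, 79 in experiment 1 alone, 7 in experiment 2 alone, 88 with weights and 16 without the 2 samples with the smallest totals. Leaving out each sample gave 116 to 131, 87 to 111, 107 to 119, 61 to 86, 115 to 131, 23 to 86 and 113 to 127 rows in that order, and 3 to 4 list results. The 23 was without viscous soft experiment 1 replicate 1, 32 without its replicate 2 and 86 without viscous soft experiment 2 replicate 2.

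List results by camera numbered 4, and 2 with the stricter filter, median centring, housekeeping scaling, no experiment term or experiment 1 alone, and 18 with labels from H to P read 2 rows down. List means were followed for the 57 results that fry called with the labels as given, and these reversed: interferon response for viscoelasticity with median centring (0.018) and the displaced labels (0.22); chemokines (-0.0122) and interferon response (-0.0201) for stiffness in elastic gels with median centring; chemokines for viscoelasticity in stiff gels with housekeeping scaling (-0.00050), experiment 1 alone (-0.0199) and without the 2 samples (-0.00504); granulocyte and progenitor for stiffness in elastic gels with labels outside H to P (-0.32) and displaced labels (-0.82); and, with displaced labels, granulocyte and progenitor for stiffness (-0.30), macrophage for the interaction (0.35) and matrix remodelling for stiffness in viscous gels (-0.11). Over all 98 list results, called or not, the displaced labels reversed 15 means, including these 5.

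Scaling shifts the median of all rows: for viscoelasticity it was -0.12 as deposited and 0.06 after median centring, and for stiffness in elastic gels 0.01 and -0.30. Directions of small changes are relative to that.

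As a replicate block in place of the experiment term, replicate numbers gave 113, 87, 106, 65, 118, 44 and 108 rows; as a random block 123, 90, 111, 67, 118, 48 and 120. Whether numbers pair samples is open, as r is mirrored in groups of 2: median r was 0.0547 in 27 same-number pairs, -0.0284 in 48 others. The edgeR fit planned for raw counts was not run, as the table holds log2 values. Voom on recovered counts gave 128, 100, 111, 67, 123, 51 and 122. Thinning to the smallest totals took the interaction from 111 to 97 rows. The tenth percentile of first-set values was 27.5 in experiment 1, which had the smaller totals in that set in most samples, and 6.56 in experiment 2, so a higher depth in experiment 1 does not account for that gap; in the second set it was 34.7 and 33.1.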

Other observations

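The tests on levels were chosen after the levels were seen. The co-variation test was written before its result.

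Levels of many rows go against their labels. A candidate explanation is that the labels from H to P are displaced by 2 rows against the values. It came from a search over 12 sets and windows of labels and displacements of up to 8 rows, 148 shares in all, and the 45 abundant and 41 restricted labels were classed after the levels had been seen. The same displacement for all labels does not account for it, since the highest share of pairs in the expected order at a displacement other than 0 was 0.751. Correct labels from H to P would give a high share, and theirs was 0.498. Read 2 rows down it was 0.946. Shuffling the classes within the block gave a p of 0.0005, the smallest that 2000 shuffles can give, over 11 displacements; it does not cover the choice of the block. Where the block begins and ends was not tested.

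The co-variation test used lists fixed before the data were examined. Across 237 pairs of a list member in the block and one outside it, the median correlation was highest of the 11 displacements at 2, at 0.346, against 0.215 for the labels as given. Random reassignment of rows gave a p of 0.0001, the smallest that 10000 draws can give. A first run, before labels were matched without regard to case, used 225 pairs, with medians of 0.352 at 2 and 0.216 at 0. The values suggest a displaced block, found and tested on the same data; the original probe list, which the table does not include, would settle it.

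If the block is read so, more lists stand out: 18 camera results against 4 with the preset correlation. With an estimated correlation none of the 18 was past the threshold (lowest adjusted p = 0.0828). The co-stimulation and dendritic cell maturation list in stiff against soft elastic gels has a mean of 1.23 and is past the threshold with the preset correlation, where the labels as given yield 0.73 and it is not. The matrix remodelling list there has 1.43, past the threshold, against 0.49. With members labelled outside H to P alone, 4 list results were past the threshold. With an estimated correlation none of these 4 was, with adjusted p-values of 0.722, 0.336, 0.475 and 0.748. The list results with displaced labels rest on a reading found and tested on the same data and are hypotheses.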
